A study of Bos taurus with 28 samples.

How the data were processed

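RNA from muscle biopsies of crossbred Aberdeen Angus x Holstein Friesian steers was measured by paired-end mRNA sequencing after poly(A) selection, per the labels' protocols. The series holds 28 libraries from 12 steers, 6 on a high energy control diet and 6 on an energy-restricted diet, each sampled at day 99 and day 131. The deposited values are raw counts of reads per Ensembl gene, 1 file per library, with 24616 gene identifiers in the same order in each and no rows for unassigned reads. Per the submitters' processing notes, the authors' tools included CASAVA version 1.4, Bowtie, SAMtools and HTSeq, and the genome build was UMD3.1. The other versions, the annotation release, the strand setting and the filters are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies can share or lose reads in ways the counts do not show.

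The technical libraries of 3 samples (7 libraries) were summed, which left 24 samples, 6 per group. Pairs of these libraries differed by less than the sampling noise over genes with at least 10 counts (chi-square per degree of freedom 0.525 to 0.807, against 14.1 to 42.5 between different steers), and each such set was counted as 1 sample. Values under 1 are below what independent counts give, and the cause is not known here. If libraries of a sample share reads, the summed totals and the floors of these 3 samples overstate their depth. Over genes with at least 10000 counts the values were 1.16 to 6.04. A sequencing run was read from the date in each file name, which gave 4 runs. Run 1 held 1 sample of each group except the restricted steers at day 131, and the other 3 runs held samples of all 4 groups.

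Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with few counts were removed with filterByExpr (minimum count 10), which left 11288 genes, and 3358 genes had 0 counts in every sample. Library sizes were scaled by TMM, dispersions were estimated with the robust option, and the 4 groups were fitted together so that they shared one estimate of the spread (biological coefficient of variation 0.417). Each of the 5 comparisons (restricted against control at each day, day 131 against day 99 within each diet, and the diet by day interaction) used the two-sided quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment at 0.05. A standard error is the size of the log2 fold change divided by the square root of the test's F. CPM values use TMM-scaled library sizes, and log2 CPM uses a prior count of 2. The principal components were taken from log2 CPM of the genes tested.

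The labels identify the animal behind each sample, so the numbers pair the 2 days of a steer. The deviations of a steer's samples from their group means correlated with a median r of 0.158 across genes (range -0.605 to 0.52), r was over 0.1 in 8 of 12 steers, and 5 of 12 correlated best with their own partner. The comparisons were fitted without a steer term, and a fit with the steer as a block was an alternative. Library totals, the percentage of counts in the 10 most abundant genes and the number of genes detected were compared by exact two-sided permutation tests in scipy 1.17.1, adjusted over 12 tests. Movement back on realimentation was measured by the correlation and covariance across genes of the restriction difference at day 99 and the later change in restricted steers. Both use the restricted day 99 samples, so they were set beside 100 reassignments of samples with group means removed, beside 100 reassignments that kept both samples of a steer together (added after the data were seen), beside 20 simulations of counts with no effect, and beside all 20 ways to give 3 of the 6 day 99 samples to each side.

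On simulated counts of 11288 genes with the real means, totals and dispersions and 200 changed genes, edgeR recovered 79% of the genes changed by 2 on the log2 scale and 19% of those changed by 1 for day 131 against day 99 in restricted steers, with 3.92% false calls. For the other comparisons it recovered 86% and 22% (restricted against control at day 99), 77% and 20% (at day 131), 76% and 21% (days in control steers), and 40% and 2% (interaction). The alternative tool DESeq2 1.42.0 gave 13.4% false calls for the days in restricted steers in the same simulation. Each gene was drawn independently, without the variation that the real samples share across genes. All these rates therefore hold for independent genes only.

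The files do not pair identifiers with names, and 0 of the 24616 identifiers matched a symbol in the reference table. The 35 gene lists fixed before the data were examined, the share of mitochondrially encoded genes and the parts of the naming rule that need symbols were therefore not run. The rule for named genes takes those past the threshold with a mean of at least 1 CPM and the largest changes, and without symbols it was held to 2 that rose and 2 that fell. Alternatives fixed before the data were examined were DESeq2, median-ratio size factors, no filter, the run as a covariate, only the groups compared, the first technical library, limma voom (limma 3.58.1) with the steer as a random effect, a replicate block with and without the run, and each sample left out in turn. A surrogate variable (sva 3.50.0) with and without the block, thinning to equal depth with and without refiltering the genes, library totals per technical library, the second library of 1 sample and the omission of 3 samples with high TMM factors were added after the data were seen.

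Library totals ran from 3342314 to 12154066 counts (median 7850948), and sample totals from 3342314 to 24376288 (median 7872308). On the scale of the CPM values used here, a count of 0 allows a level of up to 1 CPM in the shallowest sample and 0.117 CPM in the deepest, taking 3 counts per sample as the floor. These floors cover counting error only, since reads copied by PCR are not independent molecules.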

Results

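Muscle expression was profiled in 12 crossbred beef steers during and after a period of reduced energy intake. Until day 99, control steers had concentrates ad libitum with 7 kg of grass silage per day, and restricted steers had grass silage ad libitum with 0.5 kg of concentrate per day. Both then received one mixed ration (80% silage, 20% concentrate), and the second biopsy on day 131 was 32 days into this realimentation. Compensatory growth is the accelerated gain of animals whose feed is restored. Each of the 4 groups held 6 steers, and the same steers were sampled on both days. Sample totals averaged 9120714 ± 3180911 counts in control steers at day 99 (SD, n = 6), 11641887 ± 6838366 in restricted steers at day 99, 8582353 ± 3963869 in control steers at day 131 and 6148341 ± 1547309 in restricted steers at day 131.

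Groups overlapped in overall expression. The first principal component held 49.1% of the variance and the second 8.04%. Group accounted for 20.1% of the spread of the first component's scores and run for 2.25%. Genes of low abundance dominated its positive end, where 73.7% of the fifth of genes with the lowest mean had positive loadings, against 19.2% of the fifth with the highest. On the second component the restricted day 99 samples all had negative scores, from -37.9 to -8.54. Each of the other groups held both negative and positive scores there, and the difference was not tested.

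**Figure D1:**
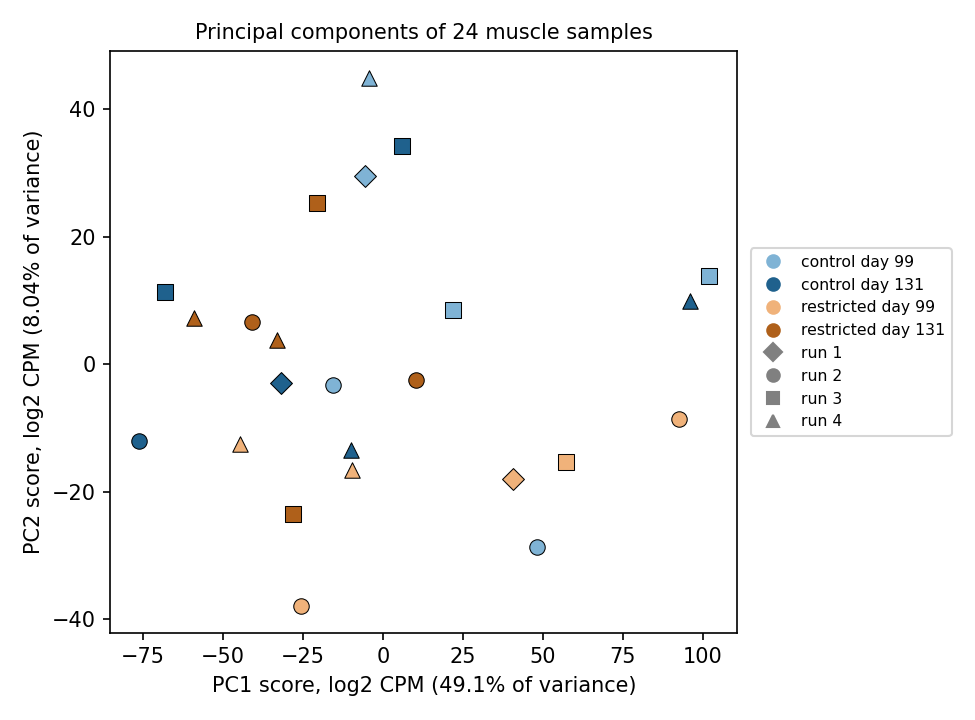
Principal component scores of the 24 muscle samples from log2 CPM, with PC1 (49.1% of variance) on the x axis and PC2 (8.04%) on the y axis. Colour gives the diet and day and the marker shape gives the sequencing run, and samples of the 4 groups and 4 runs are spread along PC1.

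Library composition did not separate the groups after adjustment. Restricted steers had fewer counts at day 131 than at day 99 (6148341 against 11641887, exact permutation p = 0.039, adjusted p = 0.462 over 12 tests, n = 6 each). Within runs, this difference was -980168 counts in run 2, -6246885 in run 3 and -3030652 in run 4, and run 1 had no restricted sample at day 131. The day 99 mean holds the sum of 3 technical libraries of restricted steer 2. Without that sample it was 9095006 counts, a difference of -2946665 (exact permutation p = 0.0779, a comparison added after the data were seen). The 10 most abundant genes held 15.6% ± 2.19 (SD, n = 6) of the counts of restricted steers at day 131 and 13.7% ± 1.47 of those of control steers (exact permutation p = 0.0974, adjusted p = 0.462). The difference was 4.13, 0.684 and 1.16 percentage points within runs 2, 3 and 4. Genes detected numbered 14899 ± 726 in restricted steers at day 131 and 15639 ± 825 at day 99 (SD, n = 6, exact permutation p = 0.121, adjusted p = 0.462), a difference of 190, -798 and -900 within runs 2, 3 and 4. The smallest adjusted p over the 12 tests was 0.462.

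The change of restricted steers from the end of restriction to day 131 addresses the response to realimentation. By edgeR's quasi-likelihood test, 43 of 11288 genes changed at an adjusted p under 0.05, of which 31 were higher and 12 lower at day 131. At an unadjusted p under 0.05 there were 2116, where no effect gives 564 on average. Genes vary together across samples, so the number with no effect can lie far from 564, and its spread was not measured. The 2116 became 1155 without the restricted steer 5 sample of day 99, 1394 without that of steer 3 and 3329 without that of steer 6. The 31 genes that rose did so by 1.3 to 6.32 on the log2 scale (median 2.30, a 4.94-fold rise), and all 31 were higher at day 131 in 6 of 6 restricted steers. They were mostly of low abundance, with a median of 2.51 CPM over the samples, and 20 of 31 lay under 5 CPM against 31.2% of all genes tested. The 12 genes that fell changed by -1.32 to -4.60 (median -2.12, a 4.36-fold fall) and had a median of 24.5 CPM. Of these, 11 were lower in 6 of 6 restricted steers and 1 was lower in 5 of 6. All 43 genes were chosen on these same samples. The choice thus raises both the sizes and the agreement between steers, which are no separate evidence.

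Among the genes that rose, ENSBTAG00000010411 went from 0.425 ± 0.383 CPM (SD, n = 6) at day 99 to 29.7 ± 38.95 CPM at day 131 in restricted steers. Its log2 fold change was 6.32 ± 1.34 (SE, edgeR adjusted p = 0.0278), and it was higher at day 131 in 6 of 6 steers. Without restricted steer 2 at day 131, at 102.7 CPM, the log2 fold change was 5.39 (adjusted p = 0.0383). At least 1 day 99 sample had 0 counts, so the fitted fold depends on the model and is no bound. The same gene was at 2.96 ± 3.83 and 7.48 ± 14.0 CPM in control steers, higher at day 131 in 4 of 6. The control rise rests on the day 131 sample of control steer 3 at 35.9 CPM, without which the log2 fold change of 1.4 turned to -0.79, and it also turned to -0.80 with the surrogate variable. ENSBTAG00000046988 went from 0.528 ± 0.692 CPM (SD, n = 6) to 6.80 ± 3.71 CPM in restricted steers, a log2 fold change of 3.75 ± 0.77 (SE, edgeR adjusted p = 0.0175), and was also at 0 counts in a day 99 sample. Without restricted steer 6 at day 99, at 1.63 CPM, the log2 fold change was 4.69 (adjusted p = 0.00709). It was higher in 6 of 6 restricted steers and in 5 of 6 control steers, whose means were 2.62 ± 1.36 and 6.04 ± 5.49 CPM.

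Among the genes that fell, ENSBTAG00000014069 went from 102.6 ± 104.9 CPM (SD, n = 6) to 9.01 ± 3.87 CPM in restricted steers, a log2 fold change of -3.49 ± 0.69 (SE, edgeR adjusted p = 0.0115). Without restricted steer 5 at day 99, at 313.4 CPM, it was -2.73 (adjusted p = 0.0591). In control steers it was at 66.7 ± 72.0 CPM at day 99 and 11.9 ± 8.99 CPM at day 131 (log2 fold change -2.47 ± 0.65, edgeR unadjusted p = 0.000737, adjusted p = 0.722). Control steer 3 at day 99 held 197.3 CPM, and the control log2 fold change ran from -2.82 to -1.51 over the alternatives. The gene was lower at day 131 in 6 of 6 restricted steers and was higher in 2 of 6 control steers. ENSBTAG00000016768 went from 3.71 ± 2.28 CPM (SD, n = 6) to 0.510 ± 0.439 CPM in restricted steers, a log2 fold change of -2.77 ± 0.63 (SE, edgeR adjusted p = 0.0363), with 0 counts in a day 131 sample and lower values in 6 of 6 steers. Its call was lost in 12 of 24 alternative fits. One was the fit with run as a covariate, where the log2 fold change was -2.91 (adjusted p = 0.0515) and so had not shrunk. The calls of ENSBTAG00000010411, ENSBTAG00000046988 and ENSBTAG00000014069 were lost in 6, 5 and 5 of 26. The log2 fold changes of the 4 genes kept their sign in all these fits.

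**Figure D2:**
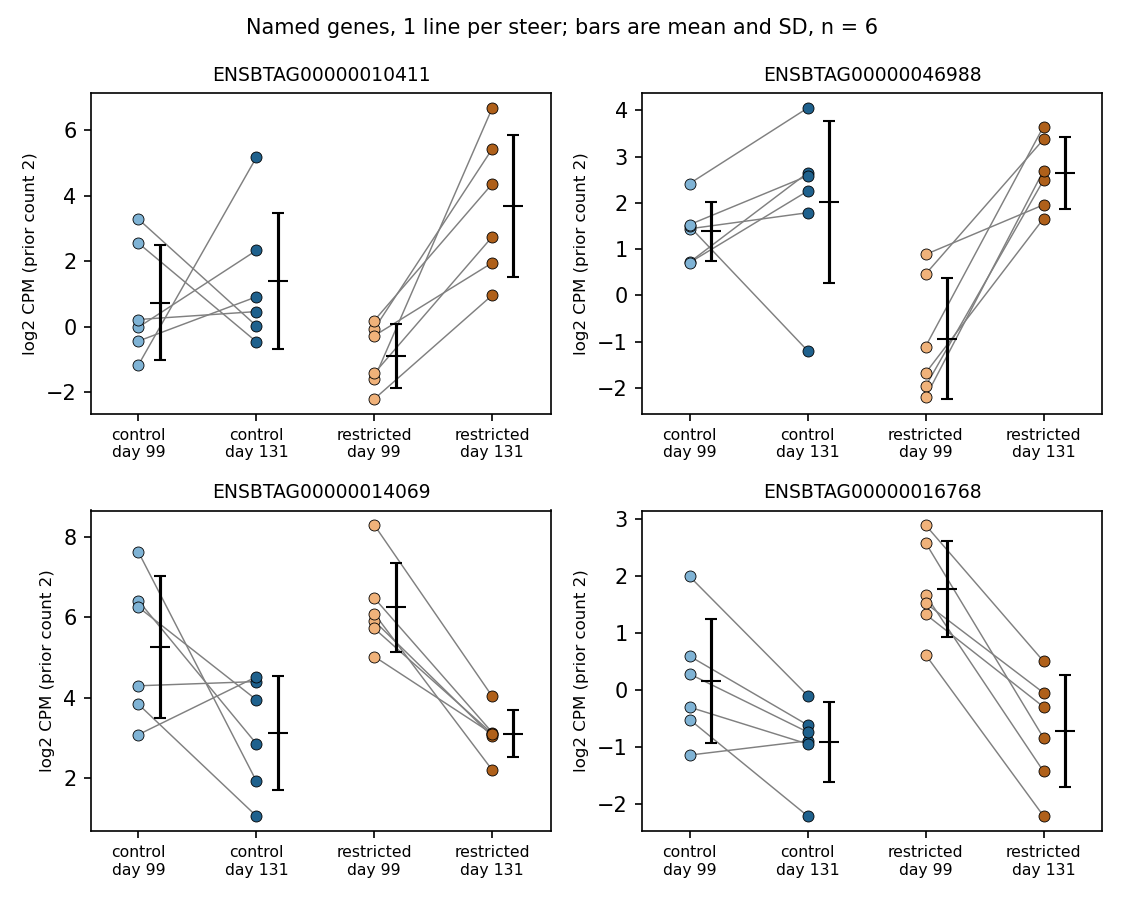
Log2 CPM (y axis, prior count 2) of the 4 named genes in each steer, by diet and day (x axis). Points are samples, grey lines join the samples of a steer, and bars show the mean and SD of 6 steers. ENSBTAG00000010411 and ENSBTAG00000046988 were higher at day 131 in 6 of 6 restricted steers, and ENSBTAG00000014069 and ENSBTAG00000016768 were lower in 6 of 6. The genes were chosen on the restricted samples.

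With run as a covariate, 32 genes were called, all among the 43. The mean log2 CPM of the 31 genes that rose was higher at day 131 by 2.01 in run 2, 2.62 in run 3 and 1.58 in run 4. That of the 12 that fell changed by -2.32, -2.06 and -1.26 in the same runs. The number of calls ranged from 21 (without the restricted steer 5 sample of day 99) to 153 (without the restricted steer 6 sample of day 99). DESeq2 called 241 genes, 162 higher and 79 lower, and a surrogate variable as a covariate gave 138, 78 higher and 60 lower.

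In control steers, 0 genes passed the same edgeR test between day 99 and day 131, with 439 at an unadjusted p under 0.05 and a smallest adjusted p of 0.722. DESeq2 and limma voom also called 0. Without the control steer 5 sample of day 131, whose TMM factor was 1.589, 3414 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0708, with 0 calls. That number was 1744 without the 3 samples with a TMM factor over 1.3. The 31 genes that rose in restricted steers had a median log2 fold change of 0.44 in control steers, where 29 lay above 0, 4 had an unadjusted p under 0.05 and 1 was higher at day 131 in 6 of 6 steers. The 12 that fell had a median of -0.29 there, where 10 lay below 0 and 4 had an unadjusted p under 0.05. Both sets were chosen on the restricted samples, so their larger change in restricted steers is partly set by the choice. The difference between the diets in their change over time, tested as the diet by day interaction, gave 0 genes by edgeR (283 at an unadjusted p under 0.05, smallest adjusted p = 0.224), 2 by DESeq2 and 0 by limma voom. It gave 48 with a surrogate variable and the steer as a block, a fit added after the data were seen. The 43 calls in restricted steers and 0 in control steers are therefore not shown to differ gene by gene in the edgeR fit fixed beforehand.

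**Figure D3:**
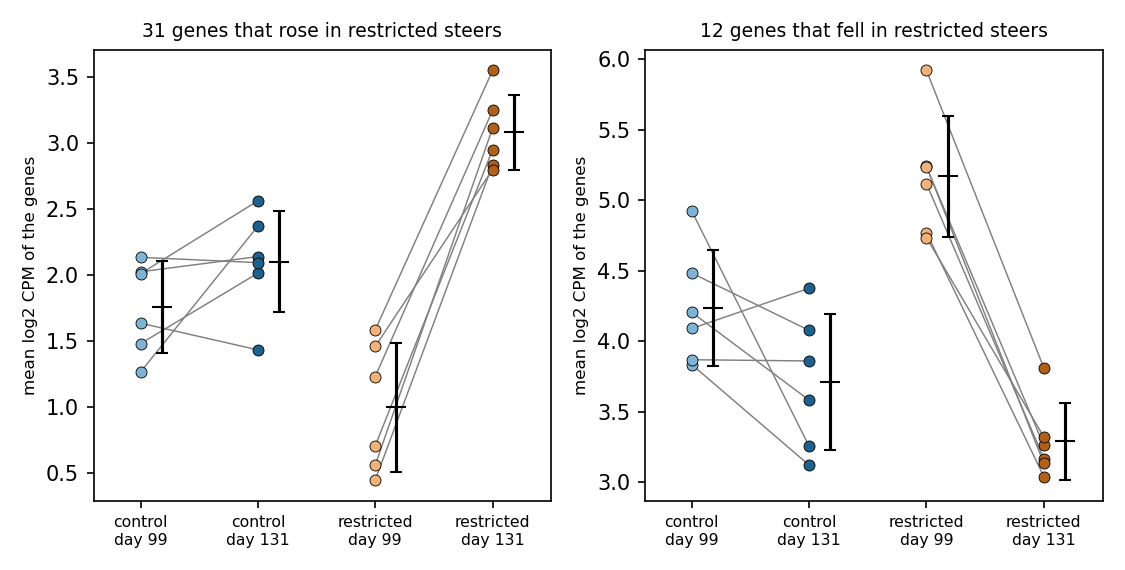
Mean log2 CPM (y axis) over the 31 genes that rose and the 12 that fell in restricted steers, for each sample by diet and day (x axis). Points are samples, grey lines join the samples of a steer and bars show the mean and SD of 6 steers. The genes were chosen on the restricted samples, whose means went from 1.00 to 3.08 for the rising genes and from 5.17 to 3.29 for the falling genes, while control means went from 1.76 to 2.10 and from 4.23 to 3.71.

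The restriction itself was compared between restricted and control steers at day 99. EdgeR's quasi-likelihood test called 0 of 11288 genes, with 486 at an unadjusted p under 0.05 (564 on average with no effect) and a smallest adjusted p of 0.0551. DESeq2 called 20 (6 higher and 14 lower in restricted steers), limma voom 1, and edgeR with median-ratio size factors 2, and edgeR with the added surrogate variable called 32. None of the 4 genes named above passed the edgeR test between diets at day 99 in the fit fixed beforehand. These genes were chosen on the restricted samples of both days. Their differences between diets at day 99 and at day 131 use those samples again. The choice therefore biases these differences and their unadjusted p-values. ENSBTAG00000046988 differed by -2.36 ± 0.76 on the log2 scale (SE, edgeR adjusted p = 0.654). Its adjusted p was 0.0269 with the added surrogate variable and 0.0269 to 1 over all alternatives. ENSBTAG00000016768 differed by 1.51 ± 0.54 (SE, edgeR adjusted p = 0.819). Its difference ran from 1.2 to 2.44 over the alternatives and was largest without control steer 3 at day 99. ENSBTAG00000010411, with 0 counts in at least 1 restricted sample, differed by -2.91 ± 1.29 (SE, unadjusted p = 0.0331, adjusted p = 1; -3.46 to -1.74 over the alternatives), and ENSBTAG00000014069 by 0.62 ± 0.62 (adjusted p = 1).

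At day 131, with both diets on one ration, edgeR called 0 genes between restricted and control steers (196 at an unadjusted p under 0.05, smallest adjusted p = 0.128). DESeq2 called 3 and limma voom 0. The largest difference of the 4 named genes was that of ENSBTAG00000010411, higher in restricted steers by 2.00 ± 1.03 on the log2 scale (SE, 4.01-fold, unadjusted p = 0.0627; 1.04 to 4.21 over the alternatives). ENSBTAG00000046988 differed by 0.23 ± 0.65, ENSBTAG00000014069 by -0.41 ± 0.64 and ENSBTAG00000016768 by 0.46 ± 0.72, and all 4 had an edgeR adjusted p of 1. In the same order, these differences ran from -0.0946 to 0.992, -0.67 to 0.0502 and -0.08 to 0.775 over the alternatives. None of them kept its sign in every fit.

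Whether expression moved back when feed was restored was examined across all 11288 genes, which are not independent replicates. The correlation of the day 99 diet difference with the later change in restricted steers was -0.311 (covariance -0.0645). Samples reassigned with no group effect gave a mean of -0.509 (95% of draws from -0.879 to 0.138; covariance -0.0703), since both differences contain the same day 99 samples. Simulated counts of independent genes with no effect gave -0.481. With the 6 day 99 samples divided 3 and 3 between the sides, the correlation averaged -0.0523 over 20 ways (range -0.486 to 0.589), against -0.00679 for reassigned samples. The covariance of the undivided samples was 0.00581 above that of the reassigned samples. With the samples divided 3 and 3 it averaged 0.0115, against -0.00487 for reassigned samples, a difference of 0.0163. Reassigning steers with both of their samples, which keeps the pairing, gave a mean correlation of -0.66 (95% of draws from -0.928 to -0.171) and a covariance of -0.0671 (-0.192 to -0.00757), and 41 of 100 draws had a covariance as low as the observed one. No movement back beyond the shared samples was detected over all genes.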

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

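The tests of run, lasting steer differences and library depth in this part were chosen after the results were seen. For distortion and background reads the predictions were written before the tests, though the patterns they address were already known.

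Run accounted for 2.25% of the scores of the wide first principal component, which argues against a run effect. Quantile normalization, which gives all samples the same distribution of values, left 46.5% of the variance in the first component (scores correlated at 0.995 with the original), so a distortion that shifts genes by abundance alone is not its whole cause. A lasting difference between steers stays open: the scores of a steer's 2 samples, as deviations from group means, gave Pearson r = -0.0534 (95% interval -0.609 to 0.537, permutation p = 0.872) and Spearman rho = 0.0979 (permutation p = 0.765) over 12 steers, and r = 0.362 without the 2 farthest steers. The component moved with library composition: its 3 highest scores (101.8, 95.9 and 92.5, for control steer 3 at day 99, control steer 5 at day 131 and restricted steer 5 at day 99) belong to the 3 highest TMM factors and the 3 lowest shares of counts in the 10 most abundant genes (10.2%, 11.4% and 10.997%). Whether RNA quality or the makeup of the biopsies lies behind this stays open.

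Samples that stood apart from their group were found in 4 of 44 groups of values tested, where chance flags about 5% of groups. Control steer 3 at day 99 had a TMM factor of 1.695 and control steer 5 at day 131 one of 1.589, both at the high end of the first component. Control steer 2 at day 131 had a total of 16115476 counts, the sum of 2 libraries of 7987792 and 8127684. The 12 genes that fell in restricted steers had a mean log2 CPM of 3.811 in restricted steer 5 at day 131, above the other 5.

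The 2 technical libraries of control steer 2 at day 131 differed in the genes they list. The first had 199 genes with at least 4 counts where the second had 0, against 5 the other way round, and between 5 and 38 in either direction in other technical pairs. It detected 16927 genes and the second 15004. Depth does not account for it, as the first holds 0.983 times the counts of the second. Reads spread evenly over genes do not either: the mean excess was 0.107 ± 0.00554 counts (SE) in 6706 genes nearly silent in the other libraries and 1.26 ± 0.0398 in 5264 expressed genes, a ratio of 0.085. Admixture of RNA from another sample stays open and was not tested, and no biological explanation was tested, since both libraries come from 1 sample.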

How the results depend on the processing

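Results with the surrogate variable, equal depth, the second library, totals per technical library or without restricted steer 2, and the omission of samples with high TMM factors were chosen after seeing the data. The direction of the 43 calls in restricted steers did not turn in any fit, but their number moved with the method. DESeq2 called 241 genes (41 of the 43 among them), limma voom 86, edgeR on only those 2 groups 92, edgeR with 1 surrogate variable 138 (38 of the 43), the surrogate variable with the replicate block 327 (171 higher, 156 lower), and the fit without the 3 samples with a TMM factor over 1.3 called 66. Thinning to equal depth called 27 genes, 21 of the 43 and 6 others. It tested 9636 genes, and 16 of the 43 fell to the filter while 6 were tested and missed the threshold. Thinning with all 11288 genes kept called 44, 32 of the 43 and 12 others. Leaving out 1 sample gave 21 to 153 (1155 to 3329 genes at an unadjusted p under 0.05, 2116 with all samples). Without restricted samples of day 99 the counts were 22 (steer 2), 24 (steer 3), 21 (steer 5) and 153 (steer 6), and 25 without steer 4 of day 131. Restricted against control at day 99 had 0 calls, 20 by DESeq2, 2 with median-ratio size factors, 1 by limma voom and 32 with the surrogate variable. It had 0 to 5 with 1 sample left out, 5 without control steer 4 and 1 without control steer 5, restricted steer 5 or restricted steer 6. At day 131, DESeq2 called 3 and all other fits 0, and 0 without any 1 sample. Control steers had 0 calls between days in every fit, 0 without any 1 sample, but the genes at an unadjusted p under 0.05 went from 439 to 3414 without control steer 5 at day 131 (smallest adjusted p 0.0708). The interaction had 2 calls by DESeq2, 3 with the surrogate variable and 48 with the surrogate variable and the replicate block, and 0 to 1 with 1 sample left out, the 1 without control steer 2 at day 131. The cause of these differences was not tested, apart from the filter and the smaller counts at equal depth. The replicate block on the steer gave 62 calls in restricted steers (36 of the 43) and 30 with the run added (25 of the 43, ENSBTAG00000016768 lost at adjusted p = 0.0624). Without the surrogate variable the block changed no other call of the 4 named genes. For restricted against control the numbers mark different steers, and a block on them gave 0 and 0 calls (r over 0.1 in 5 of 12 pairs, lowest -0.472). Without the filter 44 genes were called, 27 higher and 17 lower. Of 537 values of the 4 named genes under alternatives, 506 stayed on their side of the threshold, 28 lost a call and 3 gained one, all 3 with the surrogate variable. The correlation for movement back was -0.31 with median-ratio size factors, -0.332 without the filter and -0.349 with the run. The difference in totals between days in restricted steers was -5493545 counts, -2785069 per technical library (exact permutation p = 0.0628) and -2946665 without restricted steer 2 at day 99. The gene lists were not run for lack of names, and the 2-group fit does not exist for the interaction. At 6 steers per group, changes of 1 on the log2 scale were mostly missed in simulated counts of independent genes, with 19% recovered for the days in restricted steers.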

Other observations

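The tests of depth and of the dominant axis were chosen after the results were seen. Predictions for the rising genes in held-out steers and for other splits were written before those tests. The held-out test takes its numbers of genes, 31 and 12, from the calls, so it was set up after the calls were known. No prediction was written for the falling genes.

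Genes picked on 3 restricted steers were followed in the other 3, which entered the choice only through the filter on low counts. Control steers were part of the fit that picked the genes, through its shared spread. In each of the 20 ways to pick 3 of the 6, the 31 rising genes with the smallest p were taken and measured in the other 3. There they rose by a median of 1.54 on the log2 scale (range 0.909 to 2.25), and in control steers by 0.358 (0.22 to 0.415). The difference was 1.26 (0.758 to 1.92) and above 0 in 20 of 20 ways, although the ways overlap in steers and are not independent. Over all genes the median difference was 0.0646 (0.0232 to 0.103), also above 0 in 20 of 20 ways. The size of the difference, not its sign, thus sets the picked genes apart. Relative to control steers, the held-out restricted steers stood at -0.549 at day 99 (-1.08 to -0.059) and at 0.606 at day 131 (0.338 to 0.899). For the 12 falling genes the change was -0.832 in held-out restricted steers and -0.352 in control steers, with a difference of -0.387 (-0.752 to 0.0444). Relative to control steers they stood at 0.379 at day 99 (-0.388 to 0.753) and at -0.054 at day 131 (-0.325 to 0.198), on no single side at either day. With control steers 3 and 5 and restricted steer 5 left out of the measured values, a choice made after seeing the data, the difference was 1.27 (0.395 to 1.91) for the rising genes and -0.17 (-0.65 to 0.492) for the falling genes.

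A candidate explanation for the rising genes is therefore a response to realimentation beyond that of control steers. The difference of 1.26 in held-out steers is on the side it needs. Control steers moved from concentrates ad libitum with silage to the same ration, so that difference also holds their own change. Their change and the effect of restored feed cannot be told apart in it. At equal depth their median was 2.19 against 2.30 over all 31 genes with 0 reversed, and 21 of the 31 passed the test with the smaller counts. Thinning leaves the expected ratio between samples unchanged, so the median could hardly fall. It therefore cannot decide whether lower depth at day 131 played a part. With the surrogate variable as a covariate their median was 2.10. That variable was estimated with the group differences set aside and was not compared with the first component. The dominant axis as a cause therefore stays open. Gene by gene, the interaction had 0 calls in the edgeR fit fixed beforehand, 1 without control steer 2 at day 131, 3 with the surrogate variable and 48 with the surrogate variable and the replicate block. ENSBTAG00000010411 (adjusted p = 0.000154) and ENSBTAG00000046988 (adjusted p = 0.0435) passed in the last of these edgeR fits, against 1 for both in the first. The hypothesis is thus about the genes as a set, and restricted steers at day 131 had the lowest totals of the 4 groups. Which cells or pathways the genes belong to was not tested.

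Chance is an unlikely source of the 43 calls in restricted steers but is not excluded. Of 100 splits of the 12 samples, 1, the real one, called as many, and the highest of the others was 1. Among the 32 ways to swap days within steers, which keep every pair apart, again 1 called as many, and the highest other was 1. A share of 1 in 32 is the smallest that these swaps can give. For the remaining comparisons the real count was 0, which all 100 splits reach by construction, so these splits say nothing about chance. The highest other split called 1 gene for restricted against control at day 99 and 2 at day 131. In control steers the highest other split called 2436 genes between days, and that of the interaction 597. Such counts point to a structure of the samples. Both splits had the largest gap in first component scores of the 100 drawn (74.2 against 38.4 for the real days, and 94.3 against 8.66 for the real diets). In control steers the second largest gap, 73.8, went with 2332 calls. The gap alone does not set the count, since the second largest gap of the interaction, 88.6, went with 0, as did the largest gaps of the other 3 comparisons (53.5, 59.2 and 59.2). All 32 swaps of days within control steers, the real days included, gave 0.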
